A study of Mus musculus with 8 samples.

How the data were processed

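The 8 arrays held RNA of LY6D-negative common lymphoid progenitors from bone marrow of WT (n = 2), HEB knockout (n = 2) and E2A knockout (n = 4) mice. Per the labels' protocols the cells were sorted straight into lysis buffer, RNA was prepared with the RNeasy Micro kit, and biotin-labelled cRNA was made with a small sample protocol that amplifies the RNA over more than 1 round. Per the labels cells were pooled from several marrows in each sort, with at least 2 sorts per genotype. The p-values therefore measure the spread between arrays of pooled cells and not between mice. Whether each of the 4 E2A knockout arrays had a sort of its own is not given. The deposited values are RMA intensity values per probe set, per the submitters' processing notes, and the RMA version and chip definition are not given in the sources used here. The deposited intensity values ran on a linear scale, as their size and range show, so log2 was taken and nothing was normalized again. The number of arrays limits precision: the median SE of a log2 difference was 0.280 for E2A knockout and 0.323 for HEB knockout against WT.

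Of 45101 probe sets, 64 were controls, 34945 named a single gene, 932 named several and 9160 had no name in the annotation used here. Each of 18193 genes was represented by its probe set with the highest mean, and a gene was tested if that probe set lay above its array's median on at least 2 arrays, which kept 11957 genes and left out 6236. Signal near background makes differences look smaller, so values near the floor understate a fall. No arrays were identical, and no array was left out.

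A single limma model (version 3.58.1, R 4.3.3) with a mean per genotype was fitted to all 8 arrays with 5 residual degrees of freedom, and the 3 genotype contrasts were tested two-sided with Benjamini-Hochberg adjusted p under 0.05. "Rose", "fell" and "called" refer to this threshold. The design, the gene lists, the rule for named genes and the alternatives, apart from those named below, were fixed before the data were examined. There were 19 lists: B-lineage specification, V(D)J recombination and antigen receptor transcripts, lymphoid priming, T-lineage, Notch targets, NK and innate lymphoid, granulocyte and monocyte, dendritic cell, MHC class II presentation, mature B and plasma cell, erythroid, megakaryocyte and mast cell, stem and multipotent progenitor, E-protein and Id network, FOXO targets, IL-7 receptor and STAT5 pathway, cell cycle, interferon response, immediate early and heat shock, and sex-linked genes. The 18 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, again with a correlation estimated per list, and with fry. Some genes stand in several lists, so the lists are not independent.

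The genes named were Tcf3, Tcf12, Foxo1, Ebf1, Pax5, Rag1, Rag2, Dntt, Il7r, Flt3, Ly6d, Notch1, Gata3 and Id2 in every comparison. To these came the 8 called genes with the largest changes in each direction whose arrays did not overlap, skipping predicted genes without a name. From each list came up to 4 called members or, where there were none, the 2 with the smallest p, and shared calls had their own part of the rule. Not all of the list members chosen in this way are printed below. Further members that passed adjusted over the list alone, and Tbxa2r, were named after their values were seen.

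Shared effects of the knockouts were set against 100 simulated data sets in which neither knockout changed any gene. These drew the WT arrays too, with the residual spread of each gene, where the plan had named the real WT arrays, because knockouts drawn around the real WT means would carry no shared error. Genes near the targeted loci were placed with a RefSeq table of assembly GRCm38.p6 and compared with genes elsewhere by Fisher's exact test within 10 Mb. The scripts were tested on simulated data, 20 sets with 200 changed genes among 11957, all drawn as independent. At 2-, 4- and 8-fold they recovered 22.8%, 74.0% and 91.0% of changes for E2A knockout against WT, 11.9%, 65.7% and 86.3% for HEB knockout against WT, and 21.6%, 75.8% and 92.7% for E2A against HEB knockout. False calls made up 4.9%, 5.1% and 4.8% of calls in that order, and a lymphoid priming list shifted by -1 was found in 20 of 20 sets in each comparison.

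Alternatives were no filter or a filter at the 75th percentile, cyclic loess or median centring, the mean of or all probe sets, eBayes with trend and robust, array weights, only the compared genotypes, the first 2 numbered arrays per genotype, a replicate block, stricter thresholds and leaving out each array. Further alternatives were chosen after seeing the data: the hybridization control level as covariate, WT 2 and HEB_KO 1 both left out, the E2A knockout pools split by sex-linked signal, a crossed pairing, 1 WT array as control for each knockout, and the E-protein and Id network without the targeted genes. Where an array left out leaves a genotype with 1 array, that array is assumed to vary like the others. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.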

Results

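Gene expression was measured in common lymphoid progenitors, bone marrow cells that can still form B, T and other lymphoid cells. The cells were sorted as lineage-negative, FLT3-positive, CD127-positive and LY6D-negative, and LY6D is a surface protein whose appearance marks progenitors moving towards the B lineage. They came from C57BL/6 mice of 10 to 13 weeks that were wild type (WT), lacked HEB (the product of Tcf12) or lacked E2A (the products of Tcf3). HEB and E2A are E proteins, basic helix-loop-helix transcription factors that bind DNA as dimers and act early in lymphoid development. There were 8 arrays, 2 of WT, 2 of HEB knockout and 4 of E2A knockout cells, each labelled as a biological replicate of cells pooled from several marrows. Per the labels at least 2 independent sorts were made per genotype, so it is not settled that each of the 4 E2A knockout arrays had a sort of its own. The median intensity per array lay between 14.14 and 15.41. The upper quartile was 54.88 to 62.75 on E2A knockout arrays, 64.50 and 66.11 on WT and 68.51 and 63.32 on HEB knockout arrays. The number of arrays, above all 2 for WT and 2 for HEB knockout, limits the precision of every value below.

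At their brightest probe sets the targeted genes were lowest in the genotype labelled as lacking them. Tcf3 read 7.87 ± 0.15 (log2 intensity, SD, n = 2) in WT, 8.50 ± 0.09 (n = 2) in HEB knockout and 3.99 ± 0.24 (n = 4) in E2A knockout cells at its brightest probe set. It fell by 3.89 on the log2 scale in E2A knockout cells (14.8-fold, SE 0.22, adjusted p = 4.26e-04). Tcf12 read 8.81 ± 0.06 in WT, 8.56 ± 0.05 in E2A knockout and 6.79 ± 0.43 in HEB knockout cells, again at the brightest probe set. Its log2 difference from WT in HEB knockout cells was -2.01 (4.03-fold, SE 0.26), with both knockout arrays (7.10 and 6.49) below both WT arrays (8.85 and 8.76). That difference did not pass the threshold over all genes (adjusted p = 0.3280), while the difference between E2A and HEB knockout cells did (1.77, SE 0.22, adjusted p = 0.0372). The other probe sets moved less or otherwise. The others of Tcf3 differed by -0.70 and -0.54 in E2A knockout cells, and the mean of all its probe sets fell by 1.71. In HEB knockout cells the others of Tcf12 differed by -0.90, -1.19, -0.49 and 0.14, and 1 of them differed by 1.76 in E2A knockout cells, none past the test over all probe sets. Whether these probe sets lie inside the deleted parts of the genes is not given in the sources used here.

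Loss of E2A was compared with WT to ask which transcripts of the earliest lymphoid progenitors need this factor. Of 11957 genes tested, 47 fell and 6 rose in E2A knockout cells. Each of the 53 changed by at least 2-fold with its arrays apart from those of WT. Chance gives such a separation for 13.3% of genes, and 3039 of the 11957 tested had it. Genes called with a small spread between arrays are nearly bound to show it, so it adds no support. Genes that equip progenitors for the lymphoid lineages stood among those that fell. Ccr9, a chemokine receptor that guides progenitors to the thymus, read 8.91 ± 0.40 in WT and 3.63 ± 0.61 in E2A knockout cells, a fall of 5.28 on the log2 scale (SE 0.42, adjusted p = 0.0033). Il7r, the receptor chain for interleukin 7, fell by 2.15 (SE 0.32, adjusted p = 0.0330). Notch1, the receptor that directs T-lineage commitment, fell by 2.09 (SE 0.27, adjusted p = 0.0195). Foxo1, a transcription factor of early B-cell development, fell by 2.19 (SE 0.35, adjusted p = 0.0416). These sizes are those of the brightest probe sets, and the other probe sets of the same genes moved less. The others differed by -1.69 for Il7r, -0.63 for Notch1, -0.96, -0.65 and 0.12 for Foxo1, and -3.29, -0.18, -0.03 and 0.01 for Ccr9.

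The other genes with the largest falls were Fbp1, a gluconeogenic enzyme (-4.27, SE 0.53), Arpp21 (-4.11, SE 0.51) and Gbp8, an interferon-inducible guanylate-binding protein (-3.14, SE 0.49). Next came Fgf13 (-2.90, SE 0.40), Gimap8, a lymphocyte GTPase (-2.84, SE 0.31), and Sdc4, a heparan sulfate proteoglycan (-2.81, SE 0.46). The 6 that rose were Mtmr9 (3.09, SE 0.35), Nrp1, a co-receptor for semaphorins (2.75, SE 0.34), and Auts2 (2.67, SE 0.36), then the collagen gene Col19a1 (2.01, SE 0.26), Fxyd1, a regulator of the sodium pump (1.82, SE 0.27), and the mucin gene Muc13 (1.72, SE 0.26). The other probe sets of Mtmr9 differed by 1.94 and 2.83, and those of Nrp1 by 1.03, 1.15 and 0.88. Flt3, a sort marker, did not pass the test, with a log2 difference of -0.24 (95% interval -0.77 to 0.29). Il7r, whose fall is given above, encodes CD127, also a sort marker.

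**Figure D1:**
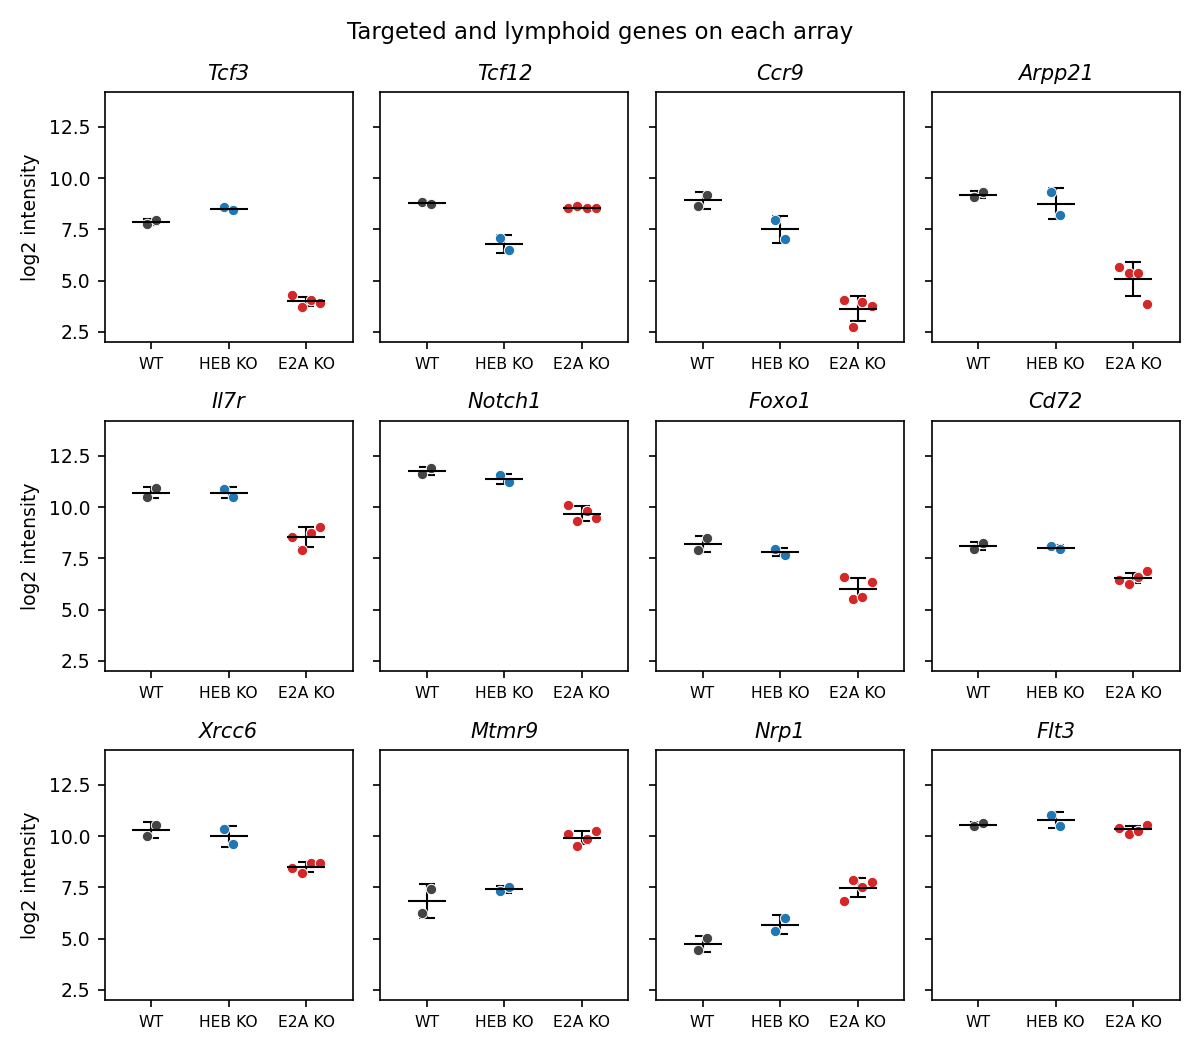
Log2 intensity (y axis) of 12 genes on each array, by genotype on the x axis, with points for arrays and bars for the mean and SD (WT n = 2, HEB knockout n = 2, E2A knockout n = 4). Tcf3, Ccr9, Arpp21, Il7r, Notch1, Foxo1, Cd72 and Xrcc6 were lower and Mtmr9 and Nrp1 higher on all 4 E2A knockout arrays than on both WT arrays, while Tcf12 was low on the 2 HEB knockout arrays.

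Lymphoid priming genes, expressed in multipotent cells before lineage choice, were lower as a group in E2A knockout cells. All 18 tested members had a negative log2 difference (median -0.71, against -0.053 over all tested genes). With the filter at the 75th percentile the median of all genes was -0.157. Of the list, 3 members, Ccr9, Il7r and Notch1, fell over all genes. In all, 11 were lower adjusted over the list alone (camera adjusted p = 2.01e-09; adjusted p = 0.0936 with an estimated correlation). Those 11 included Rag1 (-3.86, SE 0.97, and -2.07 without WT replicate 2), Rag2 (-1.43, SE 0.38) and Satb1, a chromatin organiser (-0.61, SE 0.20). Genes of V(D)J recombination, the joining of antigen receptor segments, were also lower as a group (median -0.73 over 11 members; camera adjusted p = 0.0033; adjusted p = 0.0936 with an estimated correlation). Xrcc6, which encodes the Ku70 end-joining protein, fell by 1.79 (SE 0.28, adjusted p = 0.0416). In all 6 members were lower adjusted over the list alone, among them Dntt, which adds bases at the joints (-0.96, SE 0.26), Nhej1 (-0.66, SE 0.22) and Ighm (-0.81, SE 0.24). The probe sets of Dntt did not move alike. Besides the brightest, given above, the others differed by -2.30 and 1.08, and none of them passed the test over all probe sets.

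B-lineage specification genes shifted less evenly. The list was lower as a group (median -0.17, mean -0.82 over 20 members; camera adjusted p = 0.0254; adjusted p = 0.6548 with an estimated correlation). Its mean was 5.63 on WT 1 and 6.72 on WT 2, against 5.10 to 5.74 on the E2A knockout arrays, so WT 1 lay within their range and WT 2 carried the difference. Foxo1 and Cd72, an inhibitory receptor of B cells (-1.56, SE 0.23, adjusted p = 0.0319), fell over all genes. Adjusted over the list alone 5 members were lower, these and Ebf1 (-3.06, SE 0.75, and -1.79 without WT replicate 2), the adaptor Blnk (-3.24, SE 0.56) and Bank1 (-1.86, SE 0.45). Pax5, which fixes B-cell identity, read 3.66 ± 0.16 in WT and 3.96 ± 0.16 in E2A knockout cells, a difference of 0.31 that did not pass the test. FOXO target genes were lower as a group (median -0.60 over 18 members; camera adjusted p = 0.0086; adjusted p = 0.4855 with an estimated correlation), with Foxo1 and Il7r as the 2 that fell over all genes. Adjusted over the list alone 6 of them were lower and 1 higher, Klf2 (1.92, SE 0.43).

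Interferon response genes were lower as a group in E2A knockout cells, with 16 of 17 members negative (median -0.50; camera adjusted p = 4.98e-06; adjusted p = 0.0936 with an estimated correlation). Usp18, which restrains interferon signalling (-2.44, SE 0.35, adjusted p = 0.0276), and Rtp4 (-1.74, SE 0.23, adjusted p = 0.0224) fell over all genes. A total of 6 were lower adjusted over the list alone, Oasl2 (-2.12, SE 0.44) and Gbp2 (-2.32, SE 0.42) among them. The E-protein and Id network was lower (median -0.68 over 8 members; camera adjusted p = 5.47e-04; adjusted p = 0.0936 with an estimated correlation), with Tcf3 itself the member that fell over all genes. Without Tcf3 and Tcf12, left out after seeing the data, its 6 other members had a median of -0.68 (camera adjusted p = 0.0177; adjusted p = 0.2869 with an estimated correlation). Id2, an inhibitor of E proteins, differed by -2.15 (SE 0.66), and Lyl1 by -0.79 (SE 0.20), and these 2 and Tcf3 were lower adjusted over the list alone. Stem and multipotent progenitor genes were lower as a group (median -0.48 over 16 members; camera adjusted p = 0.0064; adjusted p = 0.4364 with an estimated correlation). Adjusted over the list alone 3 of these were lower, Kit, the stem cell factor receptor (-2.08, SE 0.41), the homeobox gene Meis1 (-1.20, SE 0.24) and Angpt1 (-1.68, SE 0.42), and none fell over all genes. Cell cycle genes were higher as a group (median 0.26 over 30 members; camera adjusted p = 0.0034; adjusted p = 0.6548 with an estimated correlation) with no member past the test alone. The means of that list on the E2A knockout arrays ranged from 7.85 to 8.78, around the 7.87 and 8.03 of the WT arrays.

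The remaining lists of genes for other lineages did not pass the list test between E2A knockout and WT cells (camera adjusted p from 0.1283 to 0.7191). Members that passed only when adjusted over the list alone were Cd247 (-1.62), Lat (-1.40) and Ets1 (-1.77) among 12 T-lineage genes, and Dtx4 (-1.32) beside Notch1 among 10 Notch targets. Among 11 NK and innate lymphoid genes they were Zbtb16, the transcription factor of innate-like lymphocytes (1.53), Tox (1.49) and Id2 (-2.15). In 19 granulocyte and monocyte genes Lyz1 (-1.81), Lyz2 (-1.49), Csf1r (-1.36) and Csf3r (-0.88) were lower in this way. The dendritic cell list had Cox6a2 (-1.80), MHC class II presentation had H2-Aa (2.19), and the mature B and plasma cell list had Sdc1 (1.12) and Tnfrsf13c (-1.26). Hspa1b (-1.80) was lower among immediate early and heat shock genes, Socs2 (1.73) was higher beside the fall of Il7r in the IL-7 receptor and STAT5 list, and none passed among 16 erythroid, megakaryocyte and mast cell genes. The median was 0.15 and the mean -0.17 for granulocyte and monocyte genes, -0.09 and 0.04 for mature B and plasma cell genes, and -0.12 against an upward camera direction for the IL-7 receptor and STAT5 list. Gata3, a T-lineage factor, differed by 0.63 (SE 0.32, and 0.41 without E2A_KO replicate 4) and Ly6d by -0.09 (SE 1.40).

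**Figure D2:**
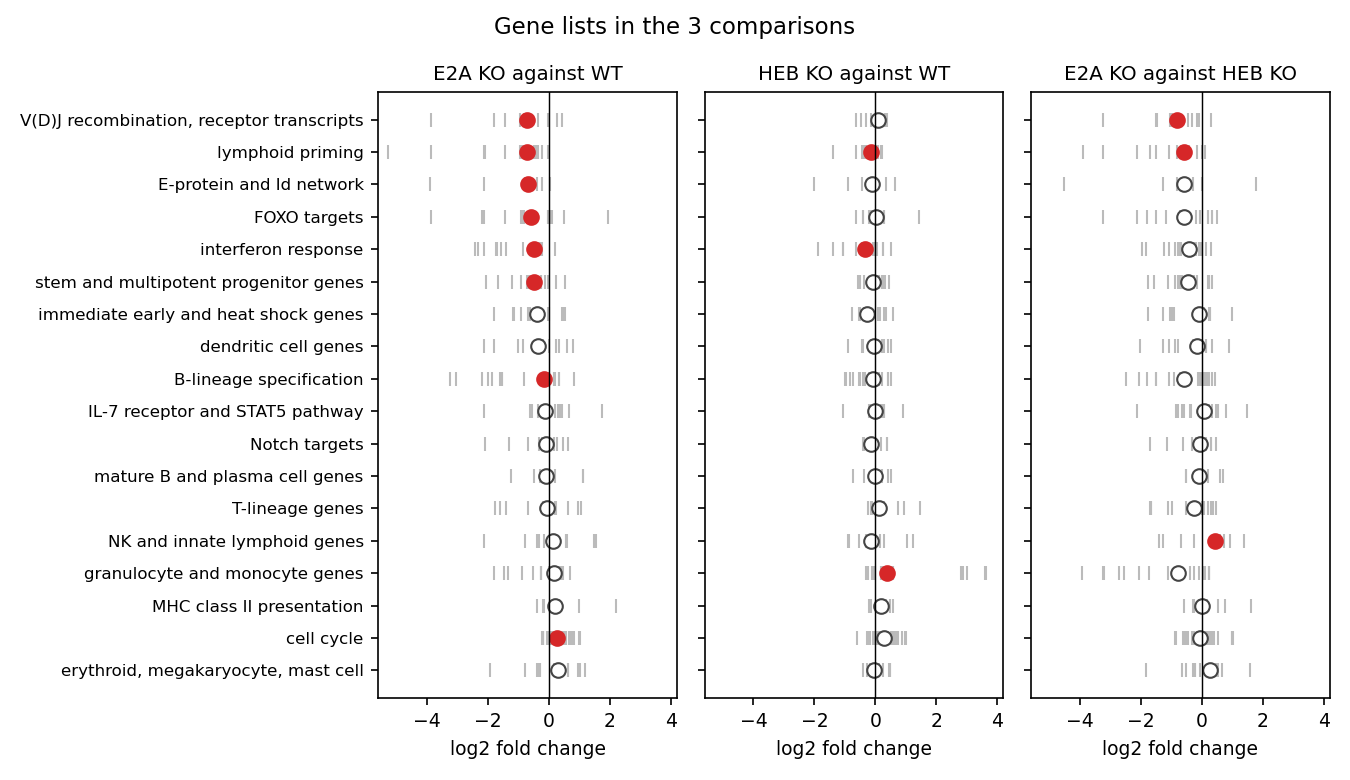
Log2 fold change (x axis) of the members (ticks) and the median (circles) of 18 gene lists (y axis) in the 3 comparisons, with filled circles for lists past the camera test at an adjusted p under 0.05. The lists passing were 8 for E2A knockout against WT, 3 for HEB knockout against WT and 3 for E2A against HEB knockout, and 0 of each passed with an estimated correlation.

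The number of called genes rested on single arrays: it was 2 without WT replicate 2, 7 without WT replicate 1, 20 without E2A_KO replicate 2, 35 without E2A_KO replicate 1, 26 without either HEB_KO array and 104 without E2A_KO replicate 3. Centring each array on its median gave 60 calls with 75% of them lower against 88.7%. The hybridization control signal was log2 11.519 to 12.622 on the E2A knockout arrays, 10.292 and 10.318 on WT 2 and HEB_KO 1, and 11.404 and 11.598 on WT 1 and HEB_KO 2. With it as a covariate, 1 gene, Tcf3, was called, an alternative chosen after seeing the data. The 47 genes that fell kept a median of -1.84 with the covariate and of -1.92 without WT replicate 2, and all 47 stayed at least 2-fold lower in both.

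Loss of HEB was compared with WT in the same cells. No gene passed the threshold with limma in this comparison. There, 312 genes had an unadjusted p under 0.05 where chance alone would give 598, but this count was 58 without WT replicate 1, 681 without WT replicate 2 and up to 1139 in other settings. The smallest adjusted p was that of Tcf12 itself. The genes that fell with loss of E2A did not pass the test here. Il7r differed by -0.02 (SE 0.37), Notch1 by -0.40 (SE 0.31) and Foxo1 by -0.39 (SE 0.40). The other probe sets differed by -0.54 for Il7r, -0.06 for Notch1 and -0.09, 0.33 and -0.03 for Foxo1. Rag2 differed by 0.08 (SE 0.44), Dntt by -0.16 (SE 0.30) and Flt3 by 0.21 (SE 0.27). Ccr9 was lower by a smaller amount that did not pass the test (-1.40, SE 0.48), and Tcf3 differed by 0.63 (SE 0.26). The other probe sets of Ccr9 differed by -1.58, -0.23, -0.13 and -0.03. Arpp21 differed by -0.42 at its brightest probe set and by -1.53, -1.41, -0.95 and -0.02 at the others. Ebf1 (-1.01, SE 0.87), Rag1 (-0.62, SE 1.12), Id2 (-0.89, SE 0.76), Pax5 (0.13, SE 0.24), Gata3 (0.17, SE 0.37) and Ly6d (-0.11, SE 1.62) did not pass either. For Ebf1, Rag1 and Ly6d the HEB knockout mean lay above WT 1 and below WT 2, so the sign rests on the WT array used.

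Interferon response genes were lower as a group in HEB knockout cells (median -0.35, with 13 of 17 members negative; camera adjusted p = 2.65e-06; adjusted p = 0.1094 with an estimated correlation). Rtp4 (-1.07, SE 0.27), Ifit1 (-1.88, SE 0.49) and Usp18 (-1.38, SE 0.40) were lower adjusted over the list alone. The actin 3' to 5' difference also moved with this comparison, at 3.371 and 3.579 on HEB knockout against 4.451 and 3.843 on WT arrays. Lymphoid priming genes were slightly lower (median -0.13 over 18 members; camera adjusted p = 0.0149; adjusted p = 0.7094 with an estimated correlation) with 0 members past the test. Their mean was 9.19 and 9.61 on the WT and 9.37 and 9.04 on the HEB knockout arrays, so the genotypes overlapped. Granulocyte and monocyte genes were higher as a group (median 0.37, mean 0.98 over 19 members; camera adjusted p = 0.0163; adjusted p = 0.7094 with an estimated correlation). The neutrophil granule genes in that list set its mean: Ltf differed by 2.87 (SE 0.85) and Camp by 2.80 (SE 1.06), neither past the test. S100a8, chosen after its values were seen, read 7.66 and 9.84 on the HEB knockout arrays, 3.35 and 6.87 on the WT arrays and 8.63 on E2A_KO replicate 3. In simulated data of the same size, which held 200 changed genes, 65.7% of 4-fold and 11.9% of 2-fold changes were recovered in this comparison. The Benjamini-Hochberg threshold is stricter where fewer genes change, so these rates do not give the share detectable here, where no gene was called. Tcf12 itself, 4.03-fold lower, did not pass (limma adjusted p = 0.3280). Changes of about 4-fold could therefore be missed, and smaller ones would mostly be missed. Without WT replicate 1 the lists past the test numbered 6, against 3 with all arrays.

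**Figure D3:**
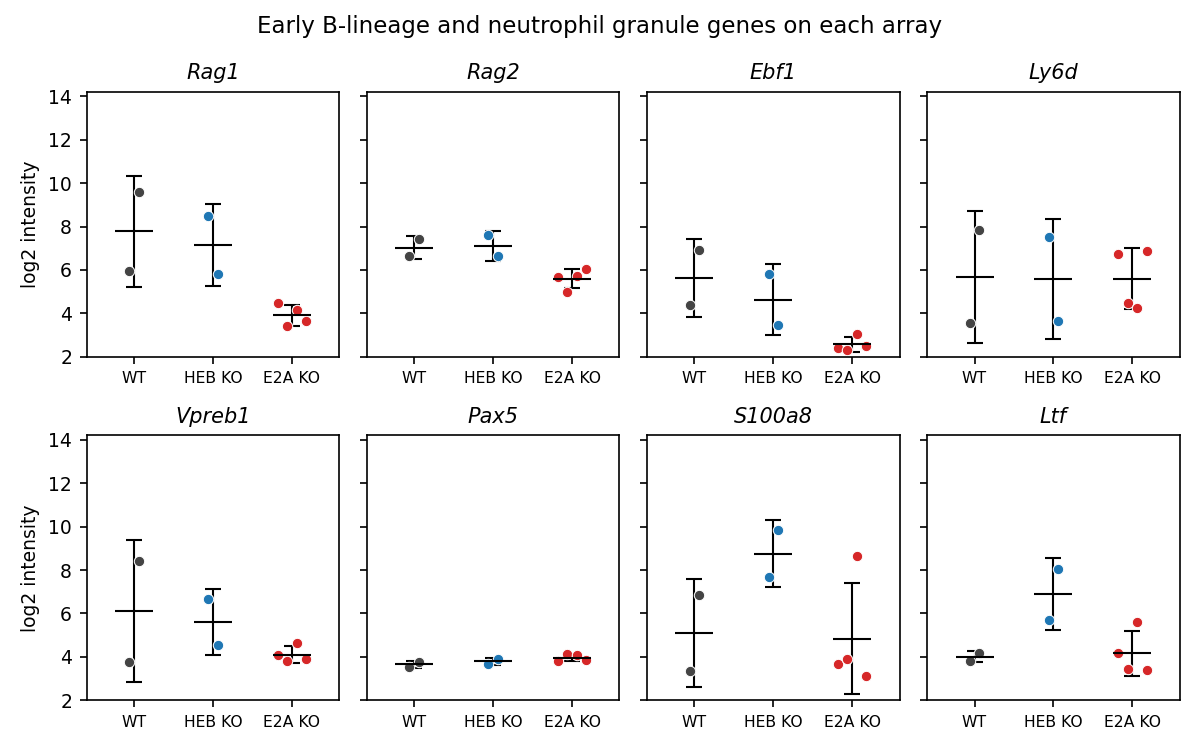
Log2 intensity (y axis) of 8 genes on each array, by genotype on the x axis, with points for arrays and bars for the mean and SD (WT n = 2, HEB knockout n = 2, E2A knockout n = 4). Rag1, Ebf1, Ly6d and Vpreb1 differed widely between the 2 WT and between the 2 HEB knockout arrays, and S100a8 reached 8.63 on a single E2A knockout array.

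E2A knockout cells were then compared with HEB knockout cells, which tests the difference between the effects of the 2 losses. In E2A knockout cells 12 genes were lower and 2 higher than in HEB knockout cells. Besides Tcf3 (-4.52, SE 0.22, adjusted p = 1.15e-04), the lower genes were led by Gbp8 (-4.19, SE 0.49), Ccr9 (-3.88, SE 0.42) and Arpp21 (-3.69, SE 0.51). The other probe sets differed less, by -1.70, 0.04, 0.05 and 0.10 for Ccr9 and by -2.38, -0.30, -0.14 and 0.10 for Arpp21. Further lower genes were Sqor, a mitochondrial sulfide oxidase (-2.37, SE 0.31), Dpy19l4 (-1.96, SE 0.23), Tanc1 (-1.92, SE 0.25) and Nabp1, a single-stranded DNA binding protein (-1.90, SE 0.25). Mtmr9 (2.51, SE 0.35, adjusted p = 0.0459) and Tcf12 were the higher ones. Ebf1 (-2.06, SE 0.75), Id2 (-1.26, SE 0.66), Flt3 (-0.45, SE 0.23), Gata3 (0.46, SE 0.32), Pax5 (0.18, SE 0.21) and Ly6d (0.02, SE 1.40) did not pass the test. Il7r (-2.13, SE 0.32, adjusted p = 0.0652), Notch1 (-1.69, SE 0.27, adjusted p = 0.0732) and Foxo1 (-1.80, SE 0.35, adjusted p = 0.0910) did not pass over all genes, though each was lower adjusted over the list alone, Il7r and Notch1 among lymphoid priming genes and Foxo1 among B-lineage genes. The difference between 3' and 5' probe sets also moved with this comparison, at 5.381 to 5.966 for Gapdh on E2A knockout arrays against 4.669 and 5.141 on HEB knockout arrays.

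Lymphoid priming genes were lower as a group in E2A than in HEB knockout cells (median -0.58 over 18 members, camera adjusted p = 2.80e-05, adjusted p = 0.3356 with an estimated correlation). Of these, 8, Il7r and Notch1 included, were lower adjusted over the list alone. All tested genes had a median of -0.163, and of -0.286 with the filter at the 75th percentile. Part of the shift was therefore not particular to the list. V(D)J recombination genes were lower too (median -0.80 over 11 members; camera adjusted p = 0.0295; adjusted p = 0.2868 with an estimated correlation), with Rag1 (-3.25, SE 0.97, and -1.90 without HEB_KO replicate 1), Rag2 (-1.51, SE 0.38), Dntt (-0.80, SE 0.26), Xrcc6 (-1.48, SE 0.28) and Nhej1 (-0.97, SE 0.22) lower adjusted over the list alone. NK and innate lymphoid genes were higher as a group (median 0.44, mean 0.13 over 11 members; camera adjusted p = 0.0295; adjusted p = 0.2868 with an estimated correlation), with Zbtb16 (1.38, SE 0.35) higher adjusted over the list alone, and turned to a median of -0.67 with a filter at the 75th percentile of each array. Their mean was 6.00 and 6.07 on E2A_KO 1 and 4, the E2A knockout arrays with higher Ly6d (6.75 and 6.88), but 5.39 and 5.45 on E2A_KO 2 and 3, against 5.75 and 5.45 on the HEB knockout arrays. Granulocyte and monocyte genes did not pass the list test (median -0.77), though Lyz1 (-1.74, SE 0.33) and Lyz2 (-2.07, SE 0.35) were among 6 lower adjusted over the list alone. The number of genes fell to 7 with each array centred on its median, of which 57.1% were lower against 85.7%, and to 10 with 70.0% lower with cyclic loess. It was 21 without E2A_KO replicate 3, 6 without either WT array, 4 without E2A_KO replicate 4, 2 without E2A_KO replicate 2 and 1 without E2A_KO replicate 1 or either HEB_KO array.

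The 2 knockouts shared no called gene, since HEB knockout had none. Of the 53 genes called in E2A knockout cells, 48 had the same sign in HEB knockout cells (90.6%), and simulated unchanged groups against common controls gave 94.7% for as many top genes. The genes that fell with loss of E2A had a median of -2.0 there and -0.42 in HEB knockout cells, and the genes that rose a median of 2.34 and 0.71. Both sets of differences share the 2 WT arrays, which alone can give medians of the same sign. No simulated value was made for these medians. Across genes, which are not independent replicates, the fold changes of the 2 knockouts correlated at r = 0.354 (Spearman rho = 0.286). This lay below the 0.575 ± 0.011 (SD over 100 simulations) of simulated data with shared WT arrays and no changed gene. The observed r was 0.554 without WT replicate 2 and 0.204 without HEB_KO replicate 2. The covariance was 0.066 against a simulated 0.093 ± 0.003, a difference of -0.026. The simulations gave all genotypes the same spread per gene and held no real change. Values below theirs therefore do not decide whether the 2 losses move the same genes. With WT 1 as control for E2A knockout and WT 2 for HEB knockout r was 0.241, and the other way round it was -0.108, an alternative chosen after seeing the data. The same sign was then found for 49 and 41 of the 53 genes.

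**Figure D4:**
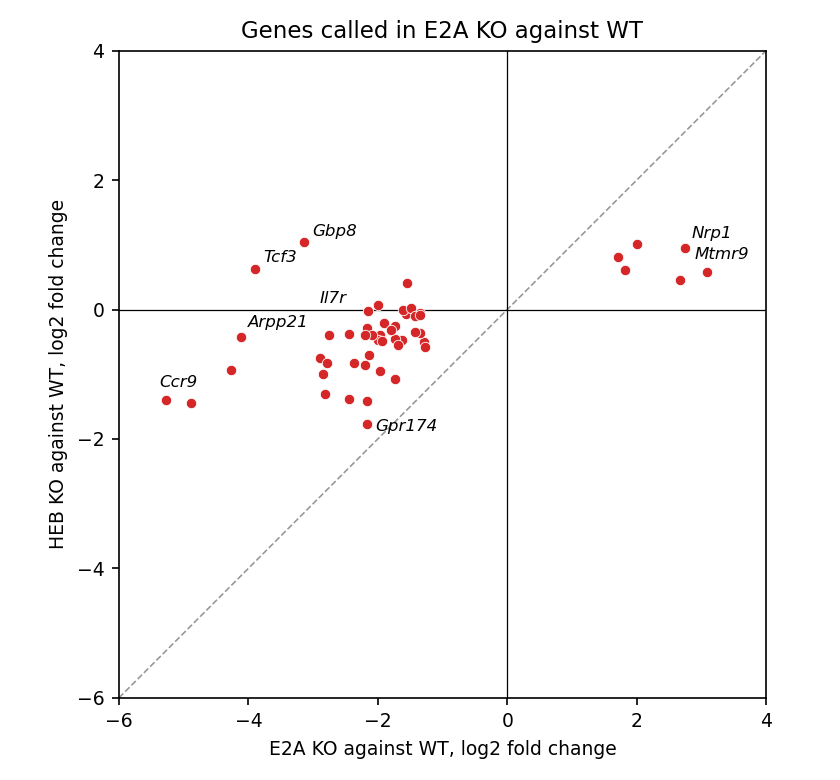
Log2 fold change of the 53 genes called in E2A knockout against WT cells (x axis) against that in HEB knockout against WT cells (y axis), with a point per gene and a dashed line of equal change. The sign is the same on both axes for 48 of 53 genes, with medians of -2.0 on the x axis and -0.42 on the y axis for the genes that fell, and 2.34 and 0.71 for those that rose. Both axes share the WT arrays.

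Genes near Tcf3 were compared with genes elsewhere. Of 214 tested genes within 10 Mb of Tcf3, 1 was called in E2A knockout cells, Tbxa2r, the thromboxane A2 receptor (-1.90, SE 0.24). Elsewhere 51 of 11722 were called (Fisher's exact test, two-sided, p = 0.6105). HEB knockout had no called gene to compare.

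Some arrays differed in ways that genotype does not name. The E2A knockout arrays lay apart from the others on the principal component that held 37.7% of the variance (6.3 to 50.3 against -37.8 to -14.0). E2A_KO replicate 3 lay farthest out and had the highest hybridization control signal (12.622). WT 2 and HEB_KO 1, with the lowest (10.292 and 10.318), lay at the other end (-34.3 and -37.8). At like signal E2A_KO 1 (11.519) scored 6.3 and HEB_KO 2 (11.598) -22.0, so the component went with both genotype and this signal. WT 2 and HEB_KO 1 correlated more closely with each other (r = 0.9883 across genes) than with the other array of their own genotype (0.9714 and 0.9742). These 2 arrays also read higher for Rag1 (9.57 and 8.49, against 5.97 on WT 1 and 5.81 on HEB_KO 2), Ebf1 (6.90 and 5.79, against 4.36 and 3.46) and Ly6d (7.83 and 7.52, against 3.53 and 3.63). Ly6d also read 6.75 and 6.88 on E2A_KO 1 and 4 and 4.48 and 4.26 on E2A_KO 2 and 3. The log2 difference between 3' and 5' probe sets of Gapdh, a sign of transcript length after amplification, was 6.026 and 4.998 in WT, 4.669 and 5.141 in HEB knockout and 5.381 to 5.966 in E2A knockout cells. That of actin was 4.451 and 3.843, 3.371 and 3.579, and 3.862 to 4.781 in the same order, so HEB knockout lay below E2A knockout arrays in both and below WT in actin. The sex-linked genes read Xist at 5.02 and 4.64 on E2A_KO 1 and 3 and at 11.61 and 11.14 on E2A_KO 2 and 4, with Y-linked Eif2s3y at 8.34, 8.21, 3.27 and 2.63 in that order, while WT and HEB knockout pools held both signals. The 3 tested sex-linked genes had a median difference of -2.30 between E2A knockout and WT cells and were not tested as a list.

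**Figure D5:**
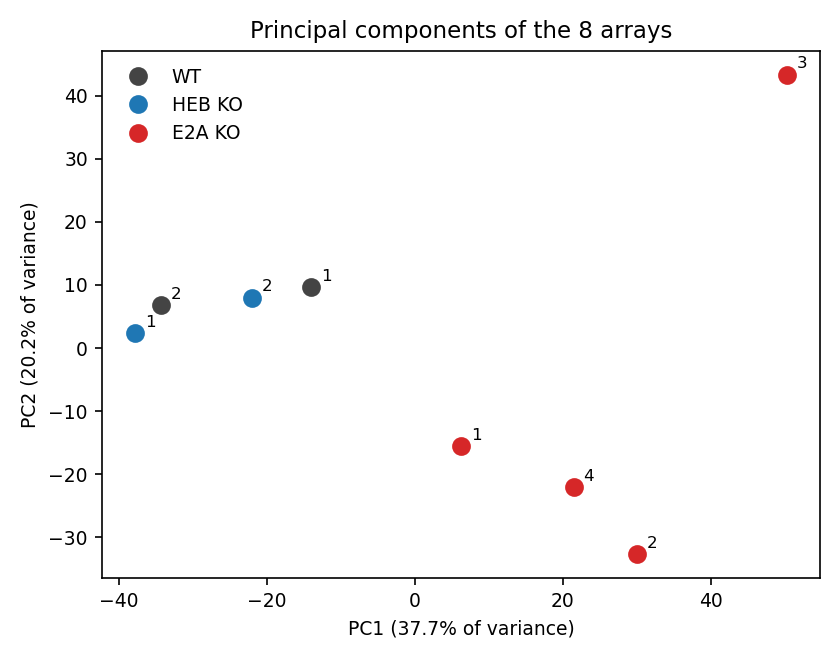
Principal component scores of the 8 arrays over 11957 genes, with the component holding 37.7% of the variance on the x axis and the next, holding 20.2%, on the y axis, coloured by genotype and numbered by replicate. The 4 E2A knockout arrays lie to the right of the WT and HEB knockout arrays, and E2A_KO replicate 3 is the farthest out. WT 2 and HEB_KO 1, the arrays with the lowest hybridization control signal, lie farthest left.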

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

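The tests on Tbxa2r and on the sex of the pools were chosen after the result was seen, as was the setting with the hybridization control level. The test on sex replaced 2 earlier ones, among them a median of -1.93 over the 47 called genes, because both chose and measured genes on the same WT arrays. Among 94 values tested over the 4 E2A knockout arrays, 3 had an array far from the others, where chance gives about 1 in 20, or 4.7. Bcl2 read 8.90 on E2A_KO 4, against 9.98 to 10.19 on the others. The mean of the lymphoid priming list was 7.88 on E2A_KO 2, against 8.24 to 8.30. The mean of the erythroid, megakaryocyte and mast cell list was 6.24 on E2A_KO 1, against 5.02 to 5.16.

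The 47 genes that fell in E2A knockout cells could reflect a technical trend, since the hybridization control signal was higher on the E2A knockout than on the WT arrays, or the sex of the pools. With the control level as a covariate their median log2 difference was -1.84 against -2.0 without it. Only 1 of them stayed past the threshold as the median SE grew from 0.27 to 0.36. These genes were called on the same arrays, which favours a small spread within genotypes, and the covariate is fitted to that spread. A kept median is thus partly built in and does not decide whether the trend was the cause. The 47 genes lowest on the pools of one sex against a single WT array had medians of -1.46 to -1.79 on the pools of the other sex against the other WT array, where all genes had -0.13 to 0.02, which argues against sex as the whole cause. Strain sequence around the targeted locus as a general cause is argued against by the 51 called genes elsewhere. Neither bound written beforehand was met, since 1 asked for no call within 10 Mb of Tcf3 and Tbxa2r lies there. With 1 call among 214 genes near Tcf3, Fisher's exact test (p = 0.6105) could not decide whether calls gather there. Loss of E2A itself stays open as the hypothesis the design names, found and tested on the same arrays.

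WT 2 and HEB_KO 1 read higher for Rag1, Ebf1 and Ly6d, which may come from a technical trend that moves all genes alike or from more cells further along the B lineage, cells that the LY6D-negative gate should remove. The whole B-lineage list, which the bound written beforehand named, lay at percentiles 100 and 99.8 of matched random lists within the 2 genotypes, but it holds genes chosen for the pattern, so the list without Ebf1 and Ly6d was used: 99.4 in WT and 92.5 in HEB knockout (median 0.23, random range -0.15 to 0.30). The granulocyte and monocyte list differed by 0.01 in WT (random range -0.10 to 0.32) and -0.49 in HEB knockout (-0.17 to 0.30), so it left the range in 1 genotype alone. Read by that bound, the 92.5 would count against more B-lineage cells. That reading was changed after the value was seen, and no spread of the median was computed that could back the change. A trend and more such cells cannot be told apart for these arrays, since the reduced list lies outside the range in WT and inside it in HEB knockout.

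Tbxa2r was the single called gene within 10 Mb of Tcf3, with a log2 difference of -1.90. Whether this could come from strain sequence beside the targeted gene or from loss of E2A cannot be told apart, because an array does not part sequence from expression.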

How the results depend on the processing

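The alternatives with the hybridization control level, WT 2 and HEB_KO 1 both left out, the E2A knockout pools split, 1 WT array per knockout and the crossed pairing were chosen after seeing the data. The genes called, 53 in E2A knockout against WT and 14 in E2A against HEB knockout, all kept their sign wherever tested. This holds for the probe set used, and Cd93 has another of opposite sign. Settings that leave out or split arrays could not change a sign, because the arrays of every called gene lay apart between the genotypes. HEB knockout against WT had 0 called genes in every setting, and shared calls stayed at 0. The count near Tcf3 was tried only with windows of 5 and 20 Mb and did not change with them. The number of called genes moved more. For E2A knockout against WT it was 91 with trend and robust, 120 with array weights, 26 with only the 2 genotypes, 3 at an adjusted p under 0.01, 1 with the control level as covariate, 0 with WT 2 and HEB_KO 1 left out, 6 with E2A_KO 1 and 3, 103 with E2A_KO 2 and 4, and 2 to 104 leaving out each array. For E2A against HEB knockout it was 7 centred, 1 with all probe sets, 42 with trend and robust, 91 with array weights, 6 with only the 2 genotypes, 3 with the first 2 numbered arrays, 1 at 0.01, 1 with the covariate, 0 with WT 2 and HEB_KO 1 left out, 1 with E2A_KO 1 and 3, 5 with E2A_KO 2 and 4, and 1 to 21 leaving out each array. Lists past the threshold numbered 0 with an estimated correlation in each comparison. Fry gave 4 for E2A knockout and 0 for HEB knockout against WT. Leaving out each array gave 5 to 9 for E2A knockout against WT, 2 to 6 for HEB knockout against WT and 1 to 6 for E2A against HEB knockout. The first 2 numbered arrays gave 5 lists for HEB knockout against WT and 8 for E2A against HEB knockout, which also had 6 with no filter, 9 with the covariate, 8 with WT 2 and HEB_KO 1 left out and 5 with E2A_KO 2 and 4. NK and innate lymphoid genes in E2A against HEB knockout reversed to a median of -0.67 with the 75th percentile filter, which tests fewer members. The correlation of the knockouts was 0.316 with no filter, 0.384 at the 75th percentile, 0.383 with cyclic loess, 0.367 with the mean of probe sets, 0.335 with the first 2 numbered arrays, 0.440 with the covariate, 0.532 with WT 2 and HEB_KO 1 left out, 0.241 with WT 1 as control for E2A knockout and WT 2 for HEB knockout, -0.108 the other way round, and 0.204 to 0.554 leaving out each array. Tcf3 in E2A knockout cells differed by -3.78 with WT 2 and HEB_KO 1 left out and lost its call (adjusted p = 0.1146), a fit with fewer arrays. Beyond the settings with fewer arrays or genes, the cause was not tested. Probe sets near background limit how large a fall can be measured.

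The labels do not say that arrays with the same number belong together, and their deviations correlated at -0.277, -0.160 and 0.082 where a pairing needs a positive value throughout, so the replicate block is no pairing. With it 12 genes were called for E2A knockout against WT and 3 genes and 7 lists for E2A against HEB knockout, with a correlation of 0.335. A crossed pairing of WT and HEB knockout arrays gave 0 genes and 5 lists, with 1139 genes at an unadjusted p under 0.05.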

Other observations

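Gene families, grouped by the stem of their symbols, were chosen and tested after the data were seen. Of 179 families with at least 8 tested members, 2, 3 and 3 passed camera in the 3 comparisons and 0 passed with an estimated correlation. Gimap genes, GTPases of lymphocytes that bear on their survival, were lower as a family in E2A knockout cells, with 8 of 8 negative (median -1.22, adjusted p = 4.05e-04; adjusted p = 0.9991 with an estimated correlation) and Gimap8 the called member. In HEB knockout cells 6 of 8 were negative (median -0.45, adjusted p = 0.0236; adjusted p = 0.9939 with an estimated correlation). Mrps genes of the mitochondrial ribosome were higher in HEB knockout cells, 27 of 29 positive (median 0.37, adjusted p = 0.0039; adjusted p = 0.9939 with an estimated correlation), as were the Psmb proteasome genes, 10 of 10 positive (median 0.43, adjusted p = 0.0236; adjusted p = 0.9939 with an estimated correlation). Their medians were 0.24 and 0.29 with each array centred. Collagen genes had a median of 0.26 in E2A knockout cells (adjusted p = 0.0346; adjusted p = 0.9991 with an estimated correlation).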
